A study of Physcomitrium patens with 21 samples.

How the data were processed

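Messenger RNA was sequenced from the stems of leafy shoots (gametophores) of the moss Physcomitrium patens, Gransden wild type, in 21 libraries that formed 7 groups of 3 biological replicates. Per the labels' protocols, polyadenylated RNA from 4 µg of total RNA went into stranded, paired-end TruSeq libraries. Bowtie2 is named in the submitters' processing notes, with no version. The genome build and the gene annotation were not given in the sources used here.

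Each library came as a table of read counts per gene model, deposited as whole numbers with no normalization. Per the file headers, the reads were parsed as pairs, single reads were treated like unmapped reads, reads that aligned equally well to several places were removed, and a pair was counted when both mates lay on the same model on opposite strands with no limit on the insert size. The tables held 32926 gene models each, in the same order and with the same lengths in all 21 libraries, and their columns summed to the totals in their headers. The deposited count of read pairs per model was the measure used here, and the count of single reads was an alternative added after the data were seen. Because multi-mapping reads were removed before counting, genes with near-identical copies are undercounted, and their values are uncertain. Whether the counting used the strand of the kit was not given in the sources used here, so reads of overlapping antisense genes may not have been separated.

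The identifiers are not paired with gene names in the tables. None of the 32926 identifiers matched the RefSeq gene table of assembly ASM5946719v1, which lists 27567 genes, so no gene was named and no coordinate was taken from it. The 30 gene lists fixed before the data were examined, among them auxin signalling, wound response, cell cycle and circadian clock genes, could not be filled, and their tests were not run.

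Counts were analysed in R 4.3.3 with edgeR 4.0.16, separately for the 15 libraries of the decapitation series and the 6 libraries of the auxin experiment, with group as the sole term. Genes with low counts were removed by filterByExpr, which left 20269 genes in the decapitation series, 19989 in the auxin experiment and 19766 in both. Library sizes were scaled by TMM, and groups were compared with the quasi-likelihood F test (glmQLFit and glmQLFTest). A gene was called when its Benjamini-Hochberg adjusted p was below 0.05. Standard errors are the log2 fold change divided by the square root of F. The common biological coefficient of variation was 0.0796 in the decapitation series and 0.0927 in the auxin experiment. Counts relative to library size (CPM) were scaled by TMM within each experiment, and log2 CPM used a prior count of 2.

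The controls were those the study names, 0 h for the decapitated groups and mock for IAA (indole-3-acetic acid). The 4 times were compared with 0 h, with each other (6 h with 2 h, 12 h with 6 h, 24 h with 12 h, 24 h with 2 h) and jointly with 0 h in an F test. The genes called higher and lower in IAA than in mock formed an auxin-raised and an auxin-lowered set. These were tested at each time with camera in limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01 and adjustment over 8 tests, and their overlap with the calls was tested with Fisher's exact test, adjusted over 32 tests. The sets were chosen on libraries that took no part in the decapitation series. By the rule for named genes, each comparison names by identifier at most 2 genes per direction, those with the largest fold change among called genes with a mean of at least 5 CPM and with all 3 libraries of a group above all 3 of the other. The tests, groups, naming rule and main alternatives were fixed before the data were examined.

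The alternatives were RLE size factors in place of TMM, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, the replicate number as a block, all 21 libraries or the 6 compared libraries in a fit, a fold change of at least 2, camera with an estimated correlation, fry, and leaving out each library in turn. The comparisons between times were given the same alternatives after the data were seen.

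Depth ran from 18995348 to 32039288 counted read pairs per library. The pipeline was tested on simulated counts drawn from the means and depths of these libraries with 200 changed genes. The changed genes were taken from those above a minimum expected count. Far more genes were called in the real comparisons, so the recovered shares need not hold there. In the simulated 12 h comparison, run on 20018 genes, 66.7% of genes changed by 0.5 on the log2 scale were recovered, 91.0% of those changed by 1 and 97.0% of those changed by 2, and 5 of 19818 unchanged genes were called. In the simulated auxin comparison, run on 19734 genes, the shares were 47.0%, 82.1% and 98.5%, and 15 of 19534 unchanged genes were called.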

Results

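The series addressed which genes are affected by auxin and by removal of the shoot tip in moss gametophores. Gametophores are the leafy shoots of mosses, which grow from an apical cell. In the decapitation series, gametophores of 4-week-old colonies were decapitated and the stems were collected at 0, 2, 6, 12 or 24 h, with 5 to 10 gametophores pooled per replicate. In the auxin experiment, gametophores were treated for 30 min with 10 µM of the auxin IAA or with solvent (mock). Plants grew at 23 °C in 16 h light and 8 h dark. The growth protocol otherwise differed between the experiments, and the sample values used give no colony age for the auxin experiment. Each of the 7 groups had 3 libraries, which the design calls biological replicates.

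The libraries held between 18995348 and 32039288 counted read pairs each. The deepest library was replicate 3 of the 24 h group. Of the gene models, 20861 had at least 1 pair in all libraries and 5991 had none in any. Between 94.6% and 96.2% of the reads of a library were mapped. Counts of replicates differed by more than sampling noise in all groups, so no library was a copy of another.

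Libraries of 1 group resembled each other more than those of other groups. Correlations across genes of log2 CPM lay between 0.987 and 0.994 within groups and reached 0.9855 at most between groups. The first principal component held 41.2% of the variance and separated the auxin experiment from the decapitation series. The second held 22.4% and ordered the decapitated stems from 0 h through 2 h and 6 h to 12 h, with 24 h back beside 0 h and 2 h. On this component the 3 IAA libraries lay on the side of 0 h and the 3 mock libraries on the side of 6 h and 12 h.

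**Figure D1:**
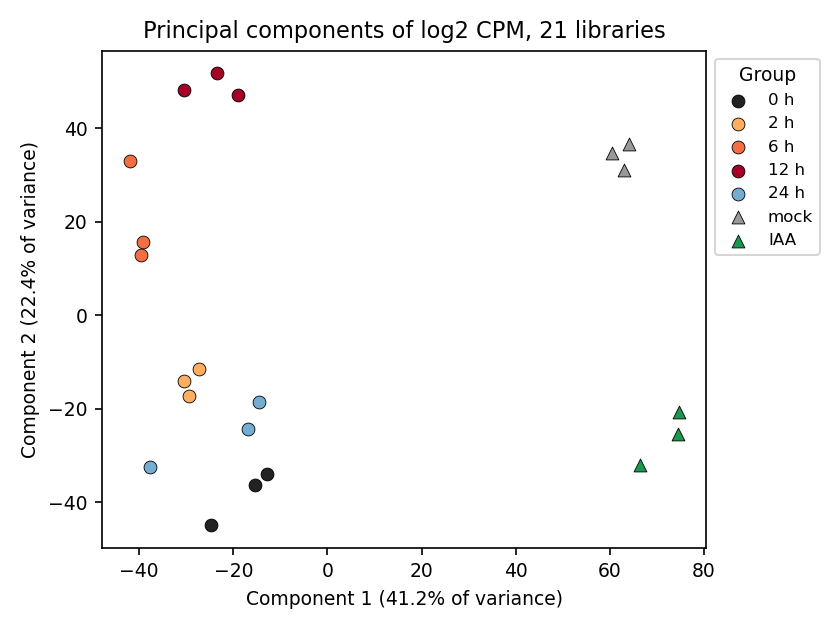
First and second principal components of log2 CPM over 20552 genes, as scores without a unit, with circles for the decapitation series and triangles for the auxin experiment. The 3 mock libraries score from 31.1 to 36.6 on component 2, and the 3 IAA libraries from -32.0 to -20.7.

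Decapitation was followed by changes in most expressed genes. Of the 20269 genes tested, 14896 (73.5%) changed at some time against 0 h in the joint edgeR test. Most changes were small. The median absolute log2 change of called genes lay between 0.34 at 2 h and 0.43 at 12 h, and the number of genes changed at least 2-fold rose from 361 at 2 h to 1171 at 6 h and 1480 at 12 h, and was 658 at 24 h. No undecapitated stems of the later hours were analysed here, and the clock hours of decapitation were not among the sample values used. If all stems were decapitated at the same hour, hour of day and hours since decapitation changed together. In that case 24 h falls at the clock hour of 0 h.

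**Figure D2:**
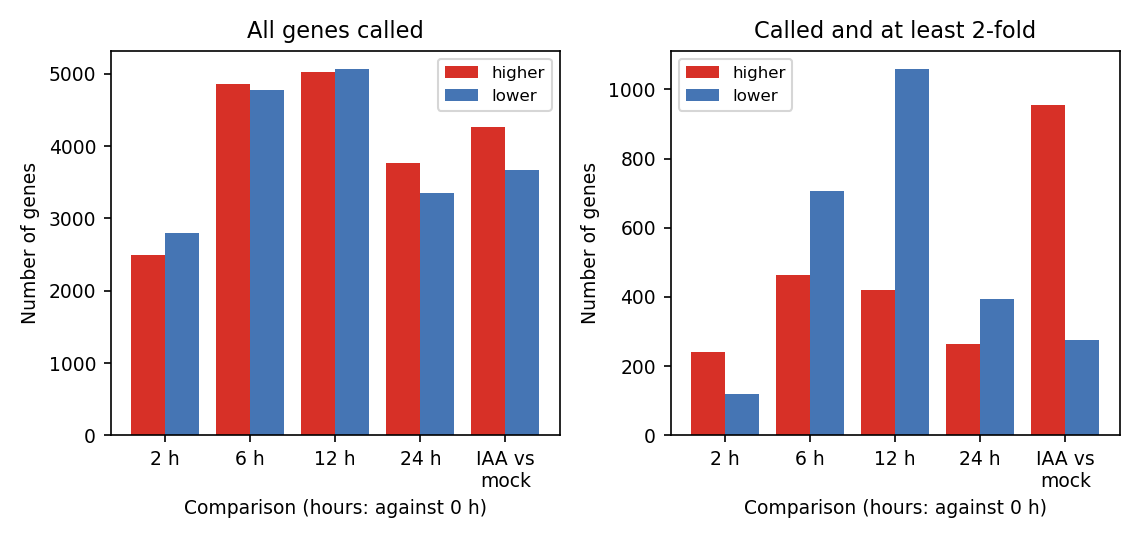
Number of genes higher (red) and lower (blue) in each comparison by the edgeR quasi-likelihood test at an adjusted p below 0.05, for all called genes (left) and for those changed at least 2-fold (right). Lower genes outnumber higher ones 1059 to 421 at 12 h among the 2-fold changes, and higher genes outnumber lower ones 955 to 277 in IAA against mock.

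At 2 h after decapitation the larger changes were mainly increases, and both of the increases named by the fixed rule were brief. A total of 242 genes were at least 2-fold higher and 119 at least 2-fold lower than at 0 h. Pp3c12_21960V3.1 rose 29.7-fold, from 1.67 CPM ± 0.354 at 0 h to 49.8 CPM ± 3.88 at 2 h (SD, n = 3 each), and stood at 2.24 CPM ± 0.237 at 6 h. Pp3c3_17840V3.1 rose 28.2-fold, from 0.488 CPM ± 0.226 to 13.9 CPM ± 2.03, and was at 1.15 CPM ± 0.439 at 6 h. Pp3c3_37540V3.1 fell 4.56-fold, from 44.3 CPM ± 4.06 to 9.73 CPM ± 2.25. The log2 changes were 4.89 ± 0.155 (SE) for Pp3c12_21960V3.1, 4.82 ± 0.312 for Pp3c3_17840V3.1 and -2.19 ± 0.124 for Pp3c3_37540V3.1, with Benjamini-Hochberg adjusted p in edgeR of 3.94e-11, 4.24e-08 and 1.04e-08.

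The fall of Pp3c12_21960V3.1 and Pp3c3_17840V3.1 after 2 h was itself tested. From 2 h to 6 h their log2 changes were -4.47 ± 0.146 and -3.59 ± 0.267 (SE; edgeR, Benjamini-Hochberg adjusted p = 3.78e-11 and 1.51e-07). At 6 h Pp3c3_17840V3.1 was still higher than at 0 h, by a log2 change of 1.23 ± 0.397 (SE; edgeR, Benjamini-Hochberg adjusted p = 0.0188), and Pp3c12_21960V3.1 was not called (adjusted p in edgeR = 0.0920). Among all 242 genes at least 2-fold higher at 2 h, 117 (48.4%) had moved back by 24 h, meaning that they were called lower at 24 h than at 2 h and were not called against 0 h, and 52 (21.5%) were still higher at 24 h. Of the 119 genes at least 2-fold lower at 2 h, 15 had moved back by 24 h and 70 (58.8%) were still lower. Without replicate 1 of 0 h, 84 genes were at least 2-fold lower at 2 h. Both times are compared with the same 0 h libraries, so part of the still-changed counts may come from them. The genes were chosen on the 2 h libraries, which the comparisons with 2 h also use. Part of the movement may come from that choice. With no threshold on the fold, 2494 genes were higher and 2795 lower at 2 h.

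Pp3c10_17490V3.1, the remaining gene named at 2 h, varied widely at 0 h. It stood at 30.9, 7.07 and 3.73 CPM in the 0 h libraries and at 2.93 CPM ± 0.529 at 2 h (SD, n = 3), a log2 change of -2.24 ± 0.689 (SE; edgeR, Benjamini-Hochberg adjusted p = 0.0255). Without replicate 1 of 0 h its log2 change was -0.88 and the adjusted p in edgeR 0.292. Without replicate 1, 2 or 3 of 2 h the log2 change stayed at -2.13, -2.22 or -2.39, while the adjusted p in edgeR was 0.0856, 0.0717 or 0.0585.

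At 6 h after decapitation, 465 genes were at least 2-fold higher and 706 at least 2-fold lower than at 0 h. Pp3c11_5230V3.1 rose 82.8-fold, from 2.94 CPM ± 0.289 to 243.7 CPM ± 6.05, and Pp3c10_16800V3.1 rose 49.8-fold, from 1.20 CPM ± 0.148 to 60.1 CPM ± 9.57 (SD, n = 3 each). Pp3c6_9870V3.1 fell 10.0-fold, from 35.5 CPM ± 8.14 to 3.54 CPM ± 1.71, and Pp3c3_9610V3.1 fell 9.26-fold, from 12.1 CPM ± 0.735 to 1.31 CPM ± 0.0939. Their log2 changes, in that order, were 6.37 ± 0.0883, 5.64 ± 0.161, -3.33 ± 0.286 and -3.21 ± 0.112 (SE), and their Benjamini-Hochberg adjusted p in edgeR 3.54e-16, 8.06e-13, 1.87e-07 and 5.62e-12.

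Most genes called at 2 h were called in the same direction at 6 h, where many more genes had changed. Of the 2494 genes higher and 2795 lower at 2 h, 1948 and 2286 were called the same way at 6 h, against 597.9 and 658.9 for independent lists, and 84 went opposite ways. The covariance of the fold changes was 0.134, against 0.0156 in simulated unchanged groups that shared simulated 0 h libraries. The simulation drew every library from the 0 h means, with each gene's spread estimated over all groups. A wider spread of the real 0 h libraries was not simulated and would raise the covariance from shared controls. Part of the excess over independent lists may come from the shared 0 h libraries, which are too few to split. From 2 h to 6 h, 126 genes were called at least 2-fold higher and 362 at least 2-fold lower, among them Pp3c11_5230V3.1, up by a further log2 3.66 ± 0.0709 (SE; edgeR, Benjamini-Hochberg adjusted p = 5.28e-14). In all, 4859 genes were higher and 4778 lower at 6 h than at 0 h.

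At 12 h after decapitation the stems differed most from 0 h, and large decreases outnumbered large increases. A total of 1059 genes were at least 2-fold lower and 421 at least 2-fold higher, and at 4-fold the numbers were 374 and 72. Pp3c11_5230V3.1 reached 314.0 CPM ± 24.2 and Pp3c10_16800V3.1 80.8 CPM ± 3.62 (SD, n = 3 each), 106.6-fold and 66.9-fold above 0 h. Pp3c12_26160V3.1 was at 15.8, 8.29 and 6.98 CPM in the 0 h libraries and had 3 read pairs over the 3 libraries of 12 h against 637 at 0 h, 213.6-fold lower with a 95% exact counting interval of 72.8 to 1039, which covers counting error alone. Pp3c16_12890V3.1 fell from 123.9, 28.9 and 11.8 CPM at 0 h to 0.318 CPM ± 0.173 at 12 h (SD, n = 3).

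The log2 changes at 12 h were 6.74 ± 0.0888 for Pp3c11_5230V3.1, 6.07 ± 0.160 for Pp3c10_16800V3.1, -7.69 ± 1.05 for Pp3c12_26160V3.1 and -7.36 ± 1.36 for Pp3c16_12890V3.1 (SE; edgeR, Benjamini-Hochberg adjusted p = 1.68e-16, 2.91e-13, 2.01e-05 and 0.000338). Without replicate 1 of 0 h the log2 change of Pp3c16_12890V3.1 was -5.93. The 3 pairs of Pp3c12_26160V3.1 at 12 h all came from replicate 1, and the other libraries of 12 h had none. Counts without a fold threshold were 5021 higher and 5067 lower.

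The genes changed most at 12 h had medians on the same side of 0 at 2 h and 6 h. The 421 genes at least 2-fold higher had median log2 changes of 0.65 at 2 h, 1.16 at 6 h, 1.33 at 12 h and 0.27 at 24 h. The 1059 genes at least 2-fold lower had medians of -0.45, -0.95, -1.60 and -0.55 at those times. Called genes shared between 6 h and 12 h numbered 3042 higher and 3151 lower, against 1204 and 1194 for independent lists. Both comparisons use the same 0 h libraries, and simulated unchanged groups gave a covariance of 0.0156 where 0.272 was observed. For 2 h and 12 h the covariance was 0.130, against 0.0157 in simulated groups, and part of each overlap and of these medians may come from the shared controls. Pp3c3_37540V3.1 ran against the trend, with 5.94 CPM ± 0.374 at 6 h and 32.5 CPM ± 3.62 at 12 h (SD, n = 3 each).

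**Figure D3:**
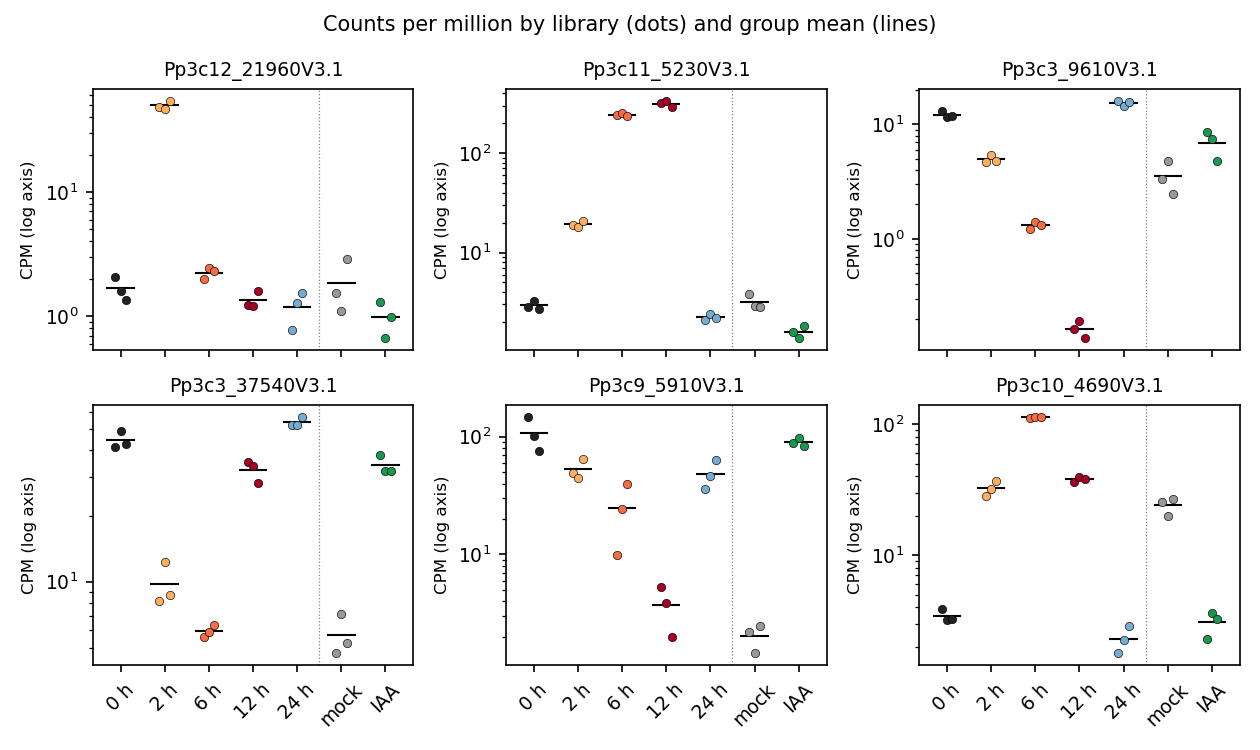
CPM on a log axis of 6 genes named by the fixed rule, with a dot per library and a line at the group mean (n = 3), scaled within each experiment, which the dotted line parts. Pp3c12_21960V3.1 peaks at 2 h with 49.8 CPM and Pp3c11_5230V3.1 at 12 h with 314.0 CPM, and Pp3c9_5910V3.1 is low at 12 h (3.73 CPM) and in mock (2.03 CPM).

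By 24 h after decapitation most of the large changes of 12 h had shrunk or gone. From 12 h to 24 h, 857 (80.9%) of the 1059 genes that had fallen were called higher, and 326 (77.4%) of the 421 that had risen were called lower. The genes were chosen on the 12 h libraries, which this comparison also uses, so part of the movement may come from that choice. Of the fallen genes, 397 (37.5%) were no longer called against 0 h after moving back, 513 (48.4%) were still lower and 91 (8.59%) had passed to the other side. Of the risen genes these numbers were 194, 143 and 38. For the fallen genes, whether more had moved back or were still lower depended on single libraries. Without replicate 1 of 0 h, 500 had moved back and 390 were still lower. Without replicate 1 of 24 h these numbers were 492 and 400. Pp3c11_5230V3.1 dropped from 314.0 CPM ± 24.2 to 2.23 CPM ± 0.153, and Pp3c3_9610V3.1 climbed from 0.164 CPM ± 0.0284 to 15.4 CPM ± 0.886 (SD, n = 3 each), log2 changes from 12 h of -7.14 ± 0.0918 and 6.50 ± 0.157 (SE; edgeR, Benjamini-Hochberg adjusted p = 1.16e-16 and 1.38e-13).

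Other changes appeared or grew from 12 h to 24 h. Against 0 h, 265 genes were at least 2-fold higher and 393 at least 2-fold lower. Of these, 166 (62.6%) of the higher and 126 (32.1%) of the lower genes had also changed in that direction from 12 h to 24 h. The genes were chosen on the 24 h libraries, which this comparison also uses, so part of these counts may come from that choice. Pp3c1_31540V3.1 rose 5.62-fold, from 34.2 CPM ± 6.38 to 191.7 CPM ± 77.5, and Pp3c2_4100V3.1 rose 4.85-fold, from 4.38 CPM ± 0.829 to 21.3 CPM ± 1.58. Pp3c6_5720V3.1 fell 9.06-fold, from 20.9 CPM ± 0.678 to 2.41 CPM ± 1.45 (SD, n = 3 each). Their log2 changes were 2.49 ± 0.389, 2.28 ± 0.193 and -3.18 ± 0.223 (SE; edgeR, Benjamini-Hochberg adjusted p = 0.000185, 1.65e-06 and 4.42e-07).

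Pp3c10_17490V3.1, also named at 2 h, was lower at 24 h by a log2 change of -3.15 ± 0.747 (SE; edgeR, Benjamini-Hochberg adjusted p = 0.00419). This was -1.80 without replicate 1 of 0 h and -3.91 without replicate 3 of 24 h, with adjusted p in edgeR of 0.0345 and 0.00838. At 12 h the log2 change of Pp3c10_17490V3.1 was -3.95 ± 0.811 (SE; edgeR, Benjamini-Hochberg adjusted p = 0.000846). From 12 h to 24 h it was not called (adjusted p in edgeR = 0.555). Over the series, 381 genes were higher and 571 lower at all 4 times, 10 and 40 of them at least 2-fold at each. All 4 comparisons share the 0 h libraries, so part of these numbers may come from them. Counts at 24 h without a fold threshold were 3769 higher and 3352 lower. The label of the 24 h group also carries a stress tag that the other times lack, with no further treatment named.

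After 30 min, the large differences between IAA and mock were mainly increases. Against mock, 955 genes were at least 2-fold higher and 277 at least 2-fold lower, and at 4-fold the numbers were 223 and 20. Pp3c9_5910V3.1 was 44.2-fold higher, with 90.0 CPM ± 7.37 in IAA and 2.03 CPM ± 0.525 in mock, and Pp3c7_13140V3.1 was 40.8-fold higher, with 75.5 CPM ± 22.3 and 1.84 CPM ± 0.836. Pp3c15_14300V3.1 was 8.49-fold lower, with 20.8 CPM ± 5.82 in IAA and 176.9 CPM ± 50.9 in mock, and Pp3c10_4690V3.1 was 7.79-fold lower, with 3.06 CPM ± 0.691 and 24.02 CPM ± 3.55 (SD, n = 3 each). The log2 changes were 5.47 ± 0.143, 5.35 ± 0.295, -3.09 ± 0.257 and -2.96 ± 0.173 (SE; edgeR, Benjamini-Hochberg adjusted p = 8.03e-08, 2.89e-06, 2.90e-05 and 4.02e-06). Without a fold threshold 4262 genes were higher and 3671 lower, of 19989 tested. The labels do not give the hours at which the IAA and mock libraries were collected.

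Genes that were at least 2-fold higher in IAA than in mock were mostly lower at 6 h and 12 h after decapitation. The 924 genes raised at least 2-fold by IAA and tested in both experiments had a median log2 change of -0.30 at 2 h, -0.64 at 6 h, -0.85 at 12 h and -0.33 at 24 h. Of them, 315 (34.1%) were called lower at 2 h, 585 (63.3%) at 6 h and 659 (71.3%) at 12 h, the last against 232.9 for independent lists (odds ratio 8.35, Fisher's exact test across genes, adjusted p = 3.17e-200). At 12 h, 59 were called higher. Fisher's test takes the genes as independent, which they are not. In camera with an estimated correlation, the Benjamini-Hochberg adjusted p of this raised set was 0.0196 at 6 h and 0.0162 at 12 h. The 269 genes lowered at least 2-fold had medians of 0.39, 0.48, 0.38 and -0.05 at those times. Of these, 127 (47.2%) were called higher at 2 h, 143 (53.2%) at 6 h and 126 (46.8%) at 12 h, and at 24 h 50 were called higher and 64 lower. Pp3c9_5910V3.1 went from 108.3 CPM ± 36.7 at 0 h to 3.73 CPM ± 1.66 at 12 h, and Pp3c10_4690V3.1 from 3.46 CPM ± 0.395 at 0 h to 113.3 CPM ± 1.41 at 6 h (SD, n = 3 each).

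The planned test used all called genes. The median log2 change of the 4226 auxin-raised genes was -0.20 at 2 h, -0.32 at 6 h and -0.30 at 12 h, and that of the 3660 auxin-lowered genes 0.14, 0.24 and 0.16. In limma's camera the Benjamini-Hochberg adjusted p was 6.61e-22, 1.06e-29 and 7.51e-21 for the raised set and 1.57e-18, 2.12e-24 and 1.22e-11 for the lowered set. All 6 calls held with an estimated correlation, at adjusted p of 1.13e-05 to 0.000124 in camera. At 24 h the medians were -0.05 and -0.03 and neither set passed (camera, Benjamini-Hochberg adjusted p = 0.292 and 0.244).

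Among the sets of at least 2-fold, the raised genes were still lower at 24 h in camera (Benjamini-Hochberg adjusted p = 1.89e-07), but not with an estimated correlation (adjusted p = 0.139). In camera this was also so at 2 h (adjusted p = 7.8e-11 and 0.0796). Under fry the raised set was called lower at both times (Benjamini-Hochberg adjusted p = 0.00304 at 24 h and 0.000483 at 2 h). At 24 h, 340 of the 924 raised genes (36.8%) were called lower, against 154.4 for independent lists (Fisher's exact test across genes, adjusted p = 2.74e-51). Across the 19766 genes tested in both experiments, the fold change by IAA and that after decapitation had a Pearson correlation of -0.39 at 2 h, -0.47 at 6 h, -0.52 at 12 h and -0.17 at 24 h. Spearman's rho was -0.44, -0.50, -0.41 and -0.05, so that by ranks 6 h was furthest from 0. These are correlations across genes, which are not independent replicates.

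**Figure D4:**
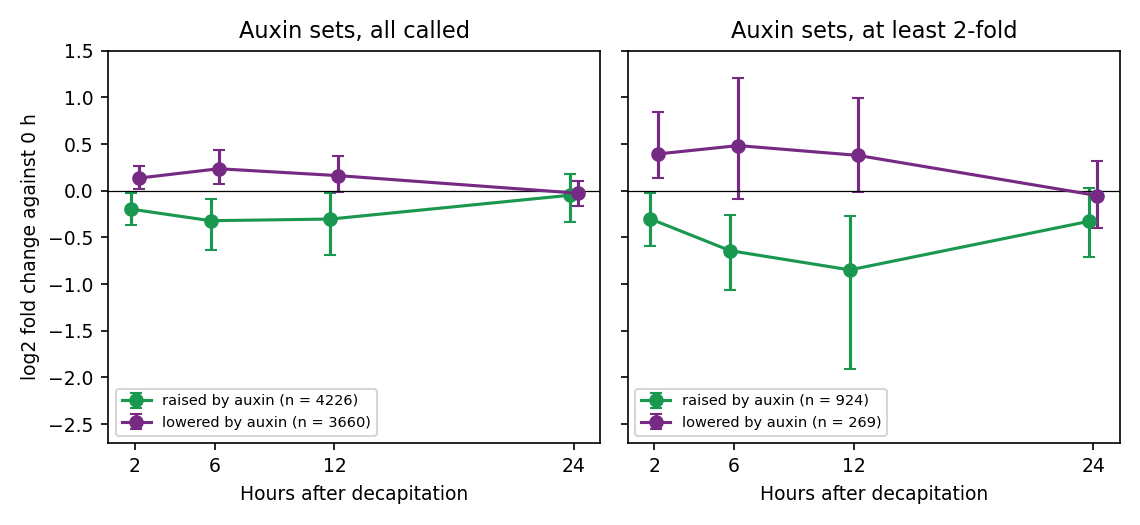
Median log2 fold change against 0 h (points) with the lower and upper quartiles over genes (bars) of genes raised (green) and lowered (purple) by IAA, by hours after decapitation, for all called genes (left) and those changed at least 2-fold by IAA (right). The raised genes of at least 2-fold have their lowest median, -0.85, at 12 h.

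The levels of these genes differed between the controls of both experiments. With all 21 libraries scaled together, the median log2 CPM of the 950 tested genes raised at least 2-fold by IAA was 4.47 ± 0.120 in IAA, 2.74 ± 0.0941 in mock and 4.19 ± 0.0998 at 0 h (SD, n = 3 each). After decapitation it was 3.85 ± 0.0791 at 2 h, 3.44 ± 0.233 at 6 h, 2.96 ± 0.0553 at 12 h and 3.80 ± 0.125 at 24 h. The 277 lowered genes had medians of 1.82 ± 0.0698 in IAA, 3.11 ± 0.114 in mock, 2.39 ± 0.0360 at 0 h and 2.94 ± 0.0474 at 2 h. The sets were chosen on the IAA and mock libraries. Levels across the experiments carry any other difference between them, such as the growth protocol.

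**Figure D5:**
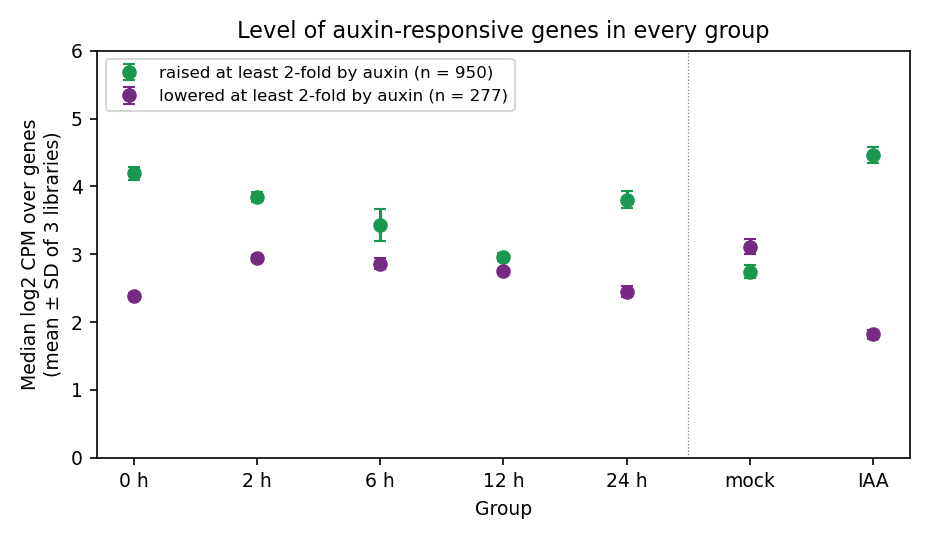
Median log2 CPM over the genes raised (green) and lowered (purple) at least 2-fold by IAA in each group, as mean and SD of 3 libraries (points and bars), with all 21 libraries scaled together and the experiments parted by the dotted line. The raised genes stand at 4.19 at 0 h and 4.47 in IAA, and at 2.96 at 12 h and 2.74 in mock.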

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

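The test of a daily rhythm and the comparison of 24 h with 6 h were chosen after the results were seen. Many genes changed in opposite directions early and at 24 h after decapitation, with the difference between the times itself called in edgeR. A total of 469 genes were higher at 2 h and lower at 24 h, and 819 were lower at 2 h and higher at 24 h. For 6 h and 24 h these numbers were 752 and 1259, and for 12 h and 24 h they were 323 and 654. Genes called in opposite directions thus numbered 1288 at 2 h and 24 h, against 932.2 for independent lists. At 6 h and 24 h they numbered 2011, against 1692. At 12 h and 24 h they numbered 977, fewer than the 1773 of independent lists. Calls in the same direction were also in excess at 2 h and 24 h, with 573 higher and 752 lower against 463.8 and 462.2. At 6 h and 24 h, 887 were higher at both times against 903.5, and 1179 were lower against 790.2. The excess of opposite calls therefore does not show that reversal was preferred.

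Among the named genes, Pp3c11_5230V3.1 had a log2 change of 6.74 at 12 h and -0.40 at 24 h, and Pp3c3_9610V3.1 one of -6.16 at 12 h and 0.34 at 24 h. Pp3c10_4690V3.1 had one of 5.03 at 6 h and -0.54 at 24 h. Pp3c2_4100V3.1 had one of -1.96 at 6 h and 2.28 at 24 h, and Pp3c6_5720V3.1 one of 0.84 at 6 h and -3.18 at 24 h. The difference between the times was called in edgeR for each of these 5 genes.

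Reads removed because they aligned equally well to several places entered no comparison. They made up 13.4% ± 0.268 of mapped reads at 24 h and 12.6% ± 0.317 at 0 h (SD, n = 3 each), and the lowest library of 24 h (13.1%) lay above the highest of 0 h (12.98%). At 6 h the share was 11.8% ± 0.248, with all 3 libraries below those of 0 h. With 3 libraries against 3, the smallest p an exact two-sided permutation test can give is 0.1.

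Of the 1480 genes changed at least 2-fold at 12 h, 1183 (79.9%) were called the other way from 12 h to 24 h. Without replicate 3 of 24 h, the deepest library, 1107 (74.8%) still were, which argues against that library as the cause. Part of the movement may come from choosing the genes on the 12 h libraries. A daily rhythm and a passing response to decapitation cannot be told apart for these genes, because no undecapitated stems of those hours were analysed here. Of the 1183 genes called the other way, 591 were no longer called against 0 h at 24 h. A response to the loss of the apex stays open and was not tested apart from time.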

How the results depend on the processing

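Under RLE scaling, no filter, a filter of 1 CPM, DESeq2, fits of all 21 or of the 6 compared libraries, single reads (chosen after the data were seen) and leaving out each library in turn, every count of higher and lower genes stayed within 1.5 times its value, and no named gene changed direction. The auxin sets, run with single reads, the replicate block, an estimated correlation, fry, sets of at least 2-fold and without each 0 h replicate, kept their direction there. The 2 h call of Pp3c10_17490V3.1 ended without replicate 1 of 0 h (1.84-fold lower against 4.74-fold with it) and without any replicate of 2 h, where the fold stayed between 4.37 and 5.25. No other named gene lost its call in these settings. Requiring a change of at least 2-fold left 242 higher and 119 lower genes at 2 h, 465 and 706 at 6 h, 421 and 1059 at 12 h, 265 and 393 at 24 h, and 955 and 277 for IAA. It left 126 and 362 from 2 h to 6 h, 251 and 482 from 6 h to 12 h, 866 and 470 from 12 h to 24 h, 274 and 547 from 2 h to 24 h, and 2298 genes at any time; fewer genes pass by construction. At 24 h the auxin-lowered set passed under fry (adjusted p = 0.0444), where camera gave 0.244 to 0.284 by correlation. The auxin-raised set of at least 2-fold passed in camera (adjusted p = 1.89e-07) and under fry (adjusted p = 0.00304). It did not pass in camera when the correlation was estimated (adjusted p = 0.139). The cause was not tested. The median of the lowered set of at least 2-fold at 24 h was -0.05, and -0.08 without replicate 3 of 24 h.

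The replicate numbers did not pair the libraries, since the deviations of same-numbered libraries from their group means correlated at down to -0.23. With the replicate number as a block, 2591 genes were higher and 2898 lower at 2 h and 4579 and 3952 for IAA. At 2 h the adjusted p of Pp3c10_17490V3.1 in edgeR was 0.0502, and no other named gene and no auxin set changed its call. DESeq2 gave no adjusted p for 786 genes at 2 h and 393 at 24 h. The tests of the 30 fixed gene lists were not run, because none of the identifiers matched the RefSeq gene table used here. Recovery in simulated counts at these depths fell to 66.7% at 2 h and 47.0% for IAA for log2 changes of 0.5, so smaller changes can be missed.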

Other observations

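The tests on gene length and expression level, on hours of collection and on daily rhythm were chosen after the results were seen. The genes that IAA raised most stood at similar levels in IAA and in stems collected at once after decapitation. These genes were chosen on the IAA and mock libraries. The growth protocol differed between the experiments, so levels compared across them also carry that difference. The 222 tested genes at least 4-fold higher in IAA had a median log2 CPM of 4.07 ± 0.229 in IAA, 3.98 ± 0.354 at 0 h, 3.52 ± 0.159 at 2 h, 1.55 ± 0.167 at 12 h and 1.08 ± 0.243 in mock (SD, n = 3 each). Of these genes, 183 (82.4%) were nearer to IAA than to mock at 0 h, 175 (78.8%) at 2 h, 146 (65.8%) at 6 h, 38 (17.1%) at 12 h and 170 (76.6%) at 24 h. In the wider set of 950 genes raised at least 2-fold, the shares were lower at 0, 2, 6 and 24 h, with 607 (63.9%), 526 (55.4%), 407 (42.8%) and 542 (57.0%), and 241 (25.4%) were nearer to IAA at 12 h. For the 277 genes lowered at least 2-fold, 174 (62.8%) were nearer to IAA at 0 h and 100 (36.1%) at 2 h.

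Genes raised at least 2-fold by IAA were lower 12 h after decapitation, with a median log2 change of -0.85. Random sets of the same length and expression level had a median of 0.0402 over 1000 draws (95% of the draws between 0.0142 and 0.0664), which argues against gene length or expression level. A daily rhythm cannot be told apart from decapitation, since no undecapitated stems of those hours were analysed here. Of the set, 305 genes were called lower at both 12 h and 24 h and 276 were back at 24 h. The clock hour of 24 h is that of 0 h only if all stems were decapitated at the same hour. At 24 h the set did not pass in camera with an estimated correlation (Benjamini-Hochberg adjusted p = 0.139), but passed under fry (adjusted p = 0.00304). A difference in the hours at which the IAA and mock libraries were collected, which the labels do not give, may also contribute. The 304 genes at least 2-fold higher at 12 h and called lower from 12 h to 24 h, back at the 0 h level or not, had a median IAA minus mock log2 change of -0.36. Its 95% interval, -0.442 to -0.279, came from a bootstrap over genes, not over libraries. The 816 genes at least 2-fold lower at 12 h and called higher from 12 h to 24 h had a median of 0.91. Opposite signs in both experiments had already been seen across all genes, so these medians cannot tell hours of collection from other causes. A loss of auxin with the apex predicts those same signs and stays open as a hypothesis.

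With 3 libraries against 3, the 10 possible splits are too few to exclude chance for a single comparison, and in each of the 9 comparisons of groups 1 of the 10 splits, the real one, gave as many called genes. The real counts were 5289, 9637, 10088 and 7121 genes at 2, 6, 12 and 24 h against 0 h, 7933 for IAA against mock, 5269 from 2 h to 6 h, 9241 from 12 h to 24 h and 8945 from 2 h to 24 h, with 0 as the highest of the other splits, and 7701 from 6 h to 12 h with 2 as the highest. For changes at any time after decapitation, 1 of 40 groupings of the 15 libraries, the real one with 14896 genes, reached that count. The highest of the others gave 2482. No share smaller than 1 in 40 can be had from this test. Groupings that mix the times can also widen the spread within groups and so lower their counts. The test covers random grouping of the libraries and no other difference between the groups. The median log2 changes of the auxin-raised genes were -0.20, -0.32, -0.30 and -0.05 at the 4 times, and the medians furthest from 0 in other splits were 0.0763, 0.125, 0.109 and 0.0325 in size. For the auxin-lowered genes they were 0.14, 0.24, 0.16 and -0.03, against 0.0550, 0.0915, 0.0683 and 0.0152. Every other split mixes libraries of both groups, which shrinks any real difference by arithmetic. The smaller medians of the other splits therefore cannot speak against chance.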
